A study of Saccharomyces cerevisiae and Mus musculus with 38 samples.

How the data were processed

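The study measured RNA, full-length transcripts, DNA, chromatin accessibility, H3K4me3 and chromosome contacts in yeast, and RNA and DNA methylation in mouse embryos. Samples were grouped from GEO's labels into 20 groups. The analysis rests on 3 deposited files of the whole series, which are 2 indices of sequence files and 1 annotation. Per the labels, the index of SynAZFa alone belongs to the yeast DNA-seq, the index of yeast sequences with SynAZFa to the yeast RNA-seq and Iso-seq, and the annotation to the embryo samples. The values in them are sequence lengths in bp, bases and bytes per line, and 1-based start and end positions of features. They are not measurements of a sample, so no depth per sample, replicate error or test between groups follows from them. Comparisons of SynAZFa with control, of nuclei with yeast and of stage with stage were not analysed here.

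The mouse lines are the GRCm38.p6 gene build, per the file headers. The submitters' processing notes name mm9 and hg18 as builds, which differs from the file header for mouse, and mouse coordinates are given here as GRCm38. The human lines name a known-gene table of hg18 as their source, on a sequence counted from its own first base. Yeast lines name RefSeq as their source. How the 3 sets were joined is not given in the sources used here. The submitters' processing notes list tools without their roles. They name GATK 3.4.0 for the yeast DNA-seq, and HISAT2 2.0.5, StringTie 2.0, deepTools 3.3.1 and R 3.6.0 for the yeast RNA-seq. HISAT2 2.1.0 stands with the Iso-seq sample in these notes, and Trimmomatic 0.36, SAMtools 1.3.1 and MACS2 2.1.1.20160309 stand with that sample and with the ChIP-seq. TopHat2 2.0.12 and HTSeq 0.6.0 are listed there for the embryo RNA-seq, and Trimmomatic (written 0.3.6) and Bismark 0.16.3 for the bisulfite sequencing. The labels disagree on the Hi-C bin size, with 10 kb in every title and 11 kb in the descriptions of the control and nuclei samples. No Hi-C value was used.

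Genes, transcripts, exons and coding parts were read from the annotation and counted by gene identifier. Of the 53918 mouse identifiers, 53832 were found in a table of gene names and 53024 had the same symbol there. Of 6464 yeast genes, 6461 were found in a table of the yeast assembly R64 and 6460 had the same start and end. The human identifiers were not paired with symbols by any table used here, and no human model was named from its identifier. The annotated extent of a sequence is its last annotated base. Human models of one strand with overlapping spans formed a locus. Exonic length is the union of the exons of all models, and introns are counted once per distinct start and end. Codons exclude the stop codon, which counts with the 3' untranslated region.

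The rule for named genes, the comparison with mouse windows and 10 of the alternatives were fixed before the data were examined. The rule names every protein-coding human model, other human models where 5 or fewer are of a kind, the mouse symbols Usp9x, Usp9y, Ddx3x, Ddx3y, Kdm6a, Utx (an older symbol of Kdm6a) and Uty, and members of 7 lists of embryo genes. Windows were drawn uniformly over the annotated extent of all mouse chromosomes (10000 windows, seed 1), and a gene counted when it overlapped a window by at least 1 base. The human value was ranked among the windows on both sides. This rank describes the annotation and is not a test over samples. Tested on 500 simulated windows with unchanged density, the ranking called 5.20% at a level of 5%. It called 100% of the simulated windows after most of their genes were removed. These windows came from 2000 simulated genes and not from the mouse annotation. Mouse windows had a median of 20 genes, with 3 at the lower and 73 at the upper percentile used below. For protein-coding genes the lower percentile was 0, so no low count could be called. The 100% therefore does not carry over to the mouse windows.

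The search for coding exon chains and the assignment of reads were chosen after the files were seen. Chains were compared by the longest common subsequence of coding exon lengths, with exact equality and, as an alternative, a tolerance of 3 bases. Chance was judged from 100 shuffles of each chain (seed 1). Tested on 200 simulated chains from mouse transcripts, with some exons lost and others changed by 3 bases, the search recovered the gene of origin in 100%. The transcripts of origin were among those searched, and a gene tied for the top count was taken as recovered. Recovery between species was therefore not tested. Differing exons were paired by a global alignment of lengths that allows an exon to be skipped. Reads of 100 bases were placed at every position along each spliced model, so each model weighs by its length and not by its expression. Alternatives used 50 and 150 bases, the strict and nonempty intersection rules, and 1 identifier per locus. Counts and lengths were called the same under an alternative when they stayed within a factor of 1.5. Calculations used Python 3.11.15, numpy 2.4.6 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9. No genome sequence was used, so no reads, models or sequences were aligned.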

Results

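The series covered 38 samples in 20 groups and followed SynAZFa, a synthetic megabase-scale copy of human DNA, from its yeast host into early mouse embryos. AZFa is a region of the long arm of the human Y chromosome whose loss is associated with male infertility, and it is known to hold USP9Y, DDX3Y and UTY. The yeast part held 23 samples of strain VL6-48, a host used for the assembly of large DNA. RNA-seq was made from 3 control and 3 SynAZFa samples, where the control carried the plasmid PRS416. ATAC-seq, which reads open chromatin, and ChIP-seq of H3K4me3, a histone mark of active promoters, each had 2 control samples, 2 SynAZFa samples and 2 samples of isolated SynAZFa nuclei. Hi-C, which reads contacts between DNA segments, had 1 sample of each of these kinds. Iso-seq of full-length transcripts and DNA-seq had 1 sample each, and the label of the DNA-seq sample gave its average depth as 400-fold.

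The mouse part held 15 samples of strain C57BL/6JNifdc. Smart-seq2, an RNA-seq protocol for very small inputs, was applied in 12 samples of parthenogenetic embryos, which develop from an egg without a sperm. There were 2 SynAZFa samples at the 1-cell stage and 2 at the 2-cell stage. The 4-cell stage and the morula each had 2 SynAZFa samples and 2 control samples of embryos that had not been injected. Whole-genome bisulfite sequencing was made from 3 samples of 1-cell SynAZFa embryos, with 20 embryos in each. The design therefore asks how SynAZFa is transcribed, packaged and folded in yeast, and how it is packaged and folded in isolated nuclei. It also asks how SynAZFa is transcribed and methylated in embryos. Values per sample for these comparisons were not analysed here, and neither was the depth of each library. The values below come from 2 indices of reference sequences and 1 gene annotation, all of the whole series, and therefore have no replicates and no replicate error.

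SynAZFa was longer than 15 of the 16 yeast nuclear chromosomes as listed in the index of yeast sequences. The lengths are those of reference sequences and were not measured in the host strain. Its entry in the index of yeast sequences was 1143493 bp long, and only chromosome IV, with 1531933 bp, exceeded it. Chromosome XV, the next in length, had 1091291 bp and 579 annotated genes, and chromosome VII had 1090940 bp and 586 genes. Chromosome I, the shortest, had 230218 bp. SynAZFa made up 8.60% of the 13300598 bp of all 18 sequences in the yeast index. A separate index of SynAZFa alone gave 1143517 bp, which is 24 bp more.

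**Figure D1:**
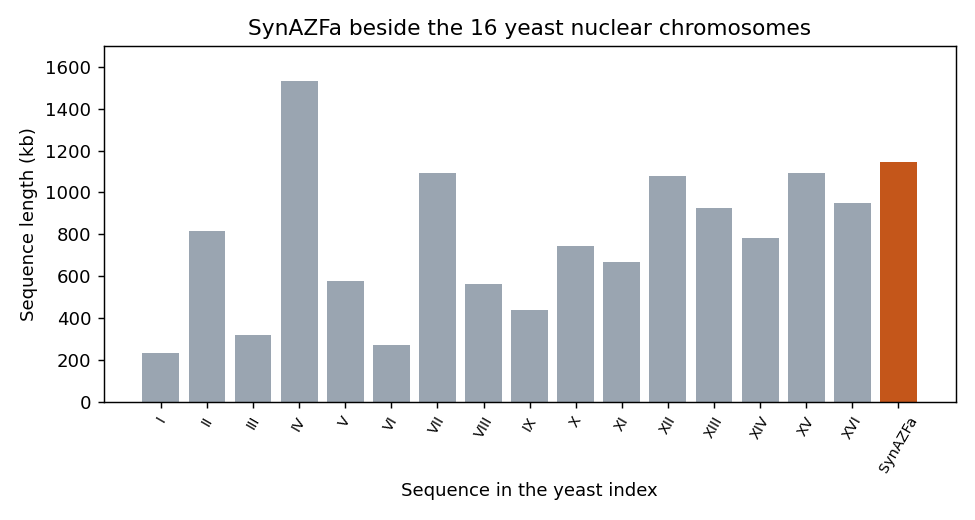
Length in kb of the 16 nuclear chromosomes of yeast (grey bars) and of SynAZFa (orange bar) in the index of yeast sequences. SynAZFa exceeds 15 of the 16 chromosomes, and chromosome IV is the exception.

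The annotation used for the embryos joined genes of 3 organisms. It held 53918 mouse genes on 20 chromosomes and the mitochondrial sequence, 6464 yeast genes on 16 chromosomes and the mitochondrial sequence, and 13 human gene identifiers on 1 sequence. The human sequence was close to mouse in the pooled median of intron length and far from yeast in exon content. Its exons took 2.42% of the annotated extent of 1149738 bp, against 4.82% in mouse and 72.7% in yeast. Introns of the human models had a median length of 1388.5 bp (100 introns), close to the 1503 bp of mouse (281132 introns) and far above the 109 bp of yeast (356 introns). The human median is pooled. In the separate loci described below it ranged from 451 bp to 2943 bp. A spliced model was annotated for 60.5% of mouse genes and 5.30% of yeast genes, and for all 13 human identifiers. Yeast had 496 protein-coding genes per Mb and mouse had 8.23.

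The 13 human models fell into 4 loci, 3 of which held a coding model. Positions are given on the human sequence of the annotation, counted from its first base, and not on a human chromosome. The human lines carried identifiers of the UCSC known genes without symbols, so loci are numbered here along the sequence. Locus 1 spanned 331486 to 361341 on the plus strand and consisted of a single model without a coding sequence, uc004fss.1, with 4 exons and 5242 exonic bp. Locus 2 spanned 370348 to 529956 on the plus strand, or 159609 bp. Locus 3 spanned 573207 to 589578 on the plus strand and was the most compact of the 3 coding loci, with 16372 bp. Locus 4 spanned 903649 to 1149738 on the minus strand and was the longest, with 246090 bp. Together the loci covered 39.3% of the annotated extent. The stretch of 331485 bp before locus 1 and the 314070 bp between loci 3 and 4 held no annotated exon, whereas loci 1 and 2 lay 9006 bp apart and loci 2 and 3 lay 43250 bp apart.

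**Figure D2:**
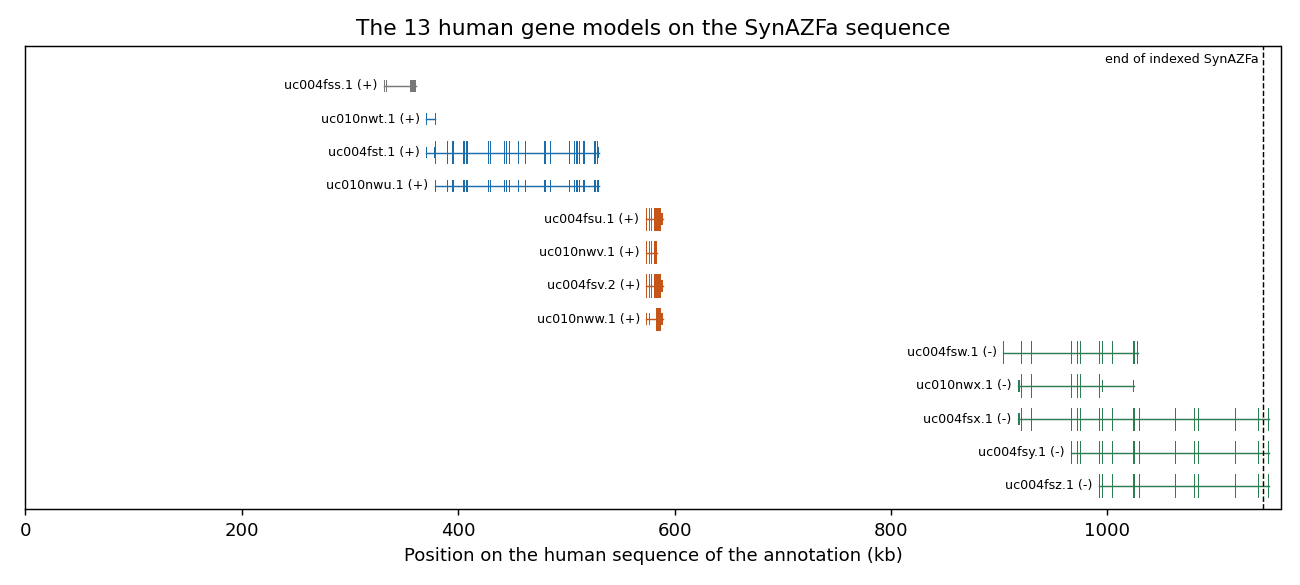
Map of the 13 human gene models along the human sequence of the annotation, with position in kb on the horizontal axis and 1 model per line, coloured by locus. Tall boxes are coding parts of exons, short boxes are untranslated or non-coding exons, very short exons are widened to stay visible, and the dashed line is the end of the index of SynAZFa alone at 1143517 bp, which locus 4 crosses.

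The coding loci differed in how much of their span was intron and in how many models they had. In locus 2, introns took 93.7% of the span. Its only coding model, uc004fst.1, had 46 exons and 2555 codons, with a 5' untranslated region of 945 bp and a 3' untranslated region of 1430 bp that includes the stop codon. The other models of locus 2, uc010nwt.1 and uc010nwu.1, had no coding sequence. In locus 3, introns took 69.6% of the span. Its 4 models were all coding, with 660 codons in uc004fsu.1 and in uc004fsv.2, 258 codons in uc010nwv.1 and 476 codons in uc010nww.1. In locus 4, introns took 96.9% of the span and the longest intron had 37302 bp. Its 5 models were all coding, and uc004fsx.1 had the most codons, 1347 in 28 exons. The others had 1240 codons (uc004fsy.1), 1083 codons (uc004fsw.1), 1079 codons (uc004fsz.1) and 404 codons (uc010nwx.1). The models of locus 4 began at 3 different first bases and ended in 4 different stop codons. All 10 coding models consisted of whole codons.

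The annotated end of locus 4 lay beyond both indexed SynAZFa sequences. The last annotated base, 1149738, was 6221 bp past the end of the index of SynAZFa alone and 6245 bp past the end of the yeast index entry. The part outside the index of SynAZFa alone held 2 exons, from 1148322 to 1148385 (64 bp) and from 1148582 to 1149738 (1157 bp). Both belonged to 3 models of locus 4, uc004fsx.1, uc004fsy.1 and uc004fsz.1. The longer of these exons held their start codon, at 1148731. The indices belong to the yeast samples per the labels, and an index of the sequence to which embryo reads were aligned was not used here.

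Of the mouse symbols looked up for the known AZFa genes, only Usp9x, Ddx3x and Kdm6a were annotated, all on the X chromosome. In GRCm38 coordinates, Usp9x (ENSMUSG00000031010), which encodes a deubiquitinase, lay at X 13071498 to 13173328 on the plus strand. Ddx3x (ENSMUSG00000000787), which encodes an RNA helicase, lay at X 13280970 to 13294052. Kdm6a (ENSMUSG00000037369), which encodes a histone demethylase, lay at X 18162575 to 18279936. The symbols Usp9y, Ddx3y and Uty had no gene in the annotation. Utx, an older symbol of Kdm6a, was not used as a symbol there. No line of the annotation lay on a mouse Y chromosome. Usp9x and Ddx3x lay 107641 bp apart with 7 genes between them, none of them protein-coding. Ddx3x and Kdm6a were 4868522 bp apart with 40 genes between them, 12 of them protein-coding. All 3 mouse genes lay on the plus strand, whereas human locus 4 lay on the other strand from loci 2 and 3.

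Each human coding locus was set beside the mouse gene that its coding exons matched best, as described in the next paragraph. The human locus had the longer span in all 3 pairs, by 1.57-fold for locus 2 over Usp9x, 1.25-fold for locus 3 over Ddx3x and 2.10-fold for locus 4 over Kdm6a. The summed exons of all models went the other way, with ratios of human to mouse of 0.668, 0.943 and 0.899. These ratios depended on the models counted. For the longest transcripts they were 0.845, 0.991 and 1.10, so locus 3 came close to equal and the direction for locus 4 turned. Usp9x had 7 annotated transcripts, Ddx3x had 5 and Kdm6a had 10, against 3, 4 and 5 human models.

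The order of coding exon lengths singled out 1 mouse gene for each human coding locus. The longest coding model of each locus was compared with all 66567 mouse coding transcripts of 22231 genes by the largest number of coding exons of exactly equal length in the same order. For locus 2, Usp9x shared 41 of 44 coding exons, and the next gene, Hmcn1, shared 10. For locus 3, Ddx3x shared 15 of 17, and the next gene, Akap9, shared 6. For locus 4, Kdm6a shared 23 of 28, and the next gene was its paralog Kdm6b with 12. When the order of each human chain was shuffled 100 times, the highest number reached over all mouse transcripts was 17, 9 and 10 for loci 2, 3 and 4, and in no shuffle was the observed number reached. The coding sequences of the best pairs had 2555 and 2554 codons, 660 and 662 codons, and 1347 and 1401 codons in human and mouse. Between these pairs of models, 11 coding exons differed in length or were lacking, 3 in locus 2, 2 in locus 3 and 6 in locus 4, and all 11 differences were multiples of 3 bases. Kdm6a has 6 coding transcripts, the longest of 1424 codons, and only the best matching transcript was compared exon by exon. Relative to that transcript, the first coding exon of uc004fsx.1 in locus 4 had 152 bases against 167. The model also lacked a coding exon of 135 bases, the mouse exon 13. Another model of the locus, uc004fsw.1, has a coding exon in that interval, from 1027532 to 1027687, which is longer than 135 bases. Whether this exon is the partner of the mouse exon cannot be told, since no sequence was compared. Hmcn1, Akap9 and Kdm6b were named after the search because they ranked second.

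**Figure D3:**
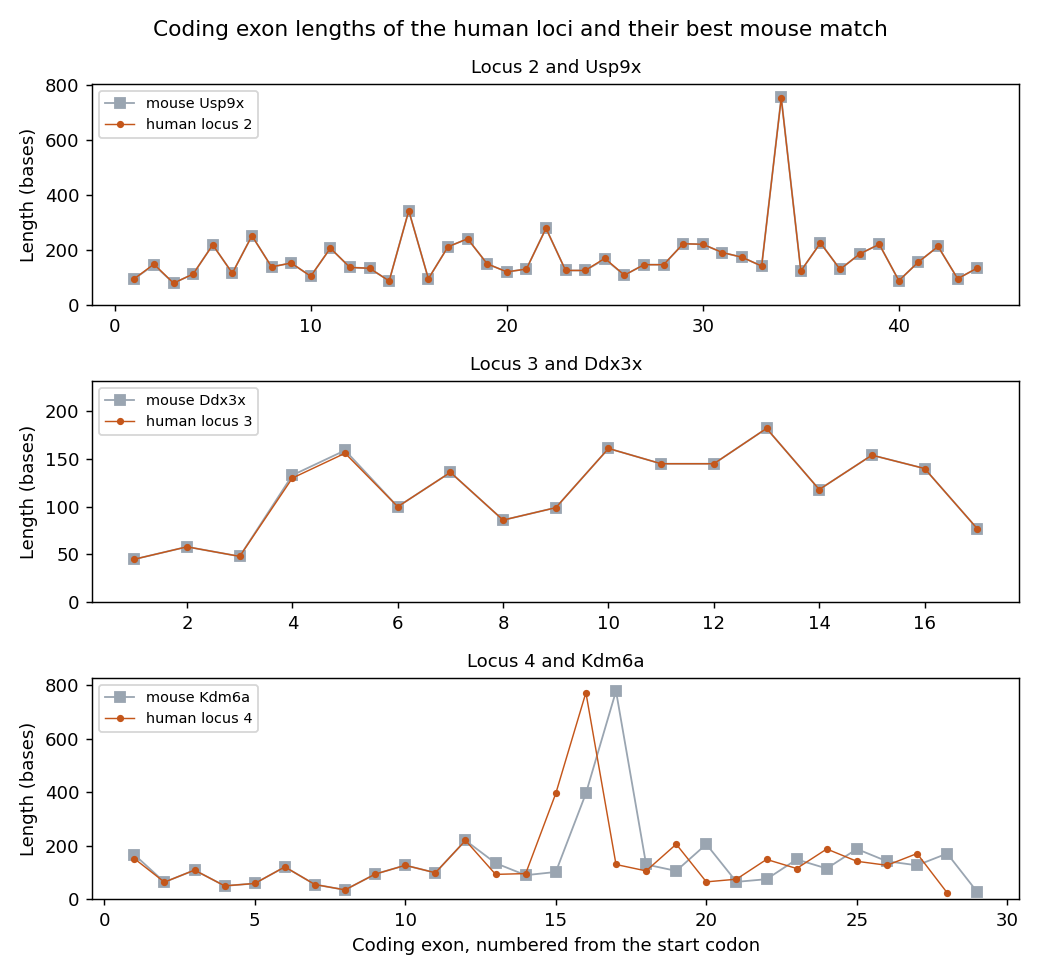
Length in bases of each coding exon, numbered from the start codon, for the longest coding model of human loci 2, 3 and 4 (orange circles) and the best matching mouse transcript (grey squares). The lengths coincide in 41 of 44 exons for Usp9x and 15 of 17 for Ddx3x, and for Kdm6a the human points are moved by 1 exon to the left after exon 12, where the mouse exon of 135 bases has no partner in the human model drawn.

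The human sequence had fewer genes than the median mouse window of its length, within the range of the windows. In 10000 random mouse windows of 1149738 bp, the median was 20 genes, with 3 at the 2.5 percentile and 73 at the 97.5 percentile. The 4 human loci were matched or undercut by 4.60% of the windows. For protein-coding genes the median window had 6, and 33.4% of windows had 3 or fewer. The exonic share of 2.42% was matched or undercut by 33.5% of windows, around a median of 3.86%. On the X chromosome alone, 3.23% of windows had 4 or fewer genes, around a median of 15, and the 4 human loci lay at the 2.5 percentile. Of the same windows, 42.1% had 3 or fewer coding genes and 57.5% had as small an exonic share. The longest stretch without an exon, 331485 bp, was at least as long as that of 84.1% of windows. None of these values lay outside the 2.5 and 97.5 percentiles of its windows. For protein-coding genes the 2.5 percentile was 0, on all chromosomes and on the X chromosome, so no low count could have lain outside. The mouse catalogue includes pseudogenes and small RNAs and the human lines come from another catalogue, so the count of genes of all kinds is not on an equal footing, and the coding count is the closer comparison.

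**Figure D4:**
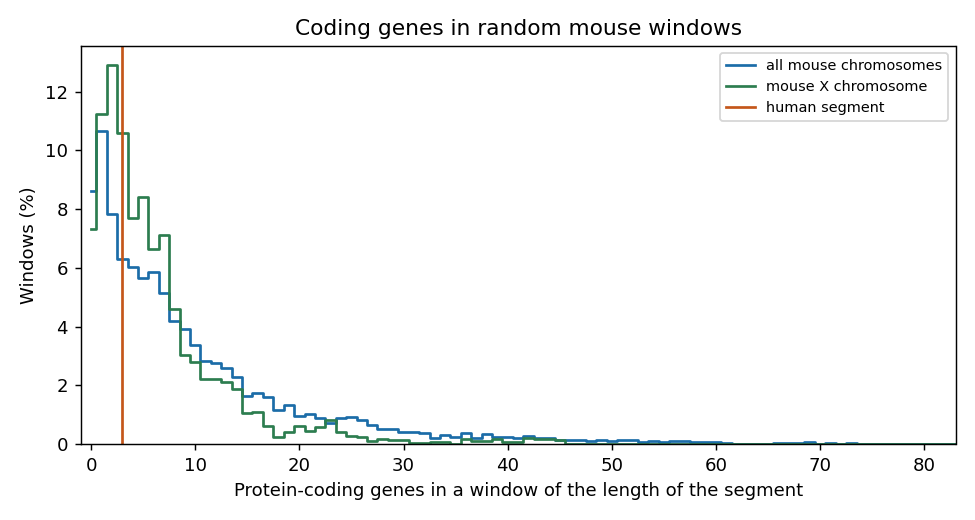
Percentage of 10000 random mouse windows of 1149738 bp (vertical axis) by the number of protein-coding genes they overlap (horizontal axis), for all chromosomes (blue line) and the X chromosome (green line). The orange line marks the 3 coding loci of the human sequence, which lie below the medians of 6 and 5 genes and within the bulk of both distributions.

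Every human model carried a gene identifier of its own, so the models of a locus overlapped as if they were separate genes. Reads of 100 bases were placed at each of the 60876 positions along the 13 models and assigned by the union rule of HTSeq, in which a read touching exons of more than 1 identifier goes to none. A single identifier took 9.94% of these positions, and 90.1% were ambiguous. In locus 1, with its single model, 100% of positions were taken. In locus 2 no position was taken, in locus 3 the share was 2.10% and in locus 4 it was 2.81%. Under the strict and nonempty intersection rules the shares of loci 2, 3 and 4 were 1.37%, 3.52% and 4.61%. For mouse Usp9x, Ddx3x and Kdm6a, whose transcripts share an identifier, 100% of positions were taken. These shares describe the annotation and are not levels of any sample. HTSeq 0.6.0 is named for the embryo RNA-seq in the submitters' processing notes, but which identifier attribute, overlap rule and read length were applied to the embryo reads is not given in the sources used here.

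Of the gene lists fixed for the embryos, most members were annotated. Presence was judged by symbol alone, so a gene annotated under another symbol would count as absent. All 6 maternal genes were present, among them Gdf9 and Bmp15, growth factors of the oocyte, and Zp3, a protein of the egg coat. Of 8 genes of zygotic genome activation, 7 were present, including Zscan4c, Zscan4d, Zscan4f and Duxf3, and the symbol Eif1ad8 was not found. All 7 blastomere and lineage genes were present, including Pou5f1 and Nanog of the pluripotent cells and Cdx2 of the trophectoderm. All 9 genes of the methylation machinery were present, including the maintenance methyltransferase Dnmt1 and the dioxygenase Tet3. All 8 imprinted genes were present, among them H19 and Igf2. All 5 mitochondrially encoded genes were present, and the mitochondrial sequence had 37 genes in all. None of the 7 mouse Y genes, such as Sry and Kdm5d, was present, which follows from the lack of any annotated line on a mouse Y chromosome. Levels of the listed genes in the embryos were not analysed here.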

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

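The chain and read results, the counting of human genes by locus, the window of indexed length, the exonic share and the longest stretch without an exon were chosen after the data were seen. Over 20 results, 38 of 52 alternative values were called the same. They kept their direction and stayed on the same side or within the factor of 1.5, or for chains kept the best mouse gene. Part of the 38 could not have differed. Locus 1 has a single model, so its longest transcript and its read shares were fixed. The strict and nonempty rules gave equal shares because reads were placed on exons only, so they are not separate checks. Counted by locus, there were 4 human genes in place of 13. With the longest single transcript, the exonic ratio of locus 4 to Kdm6a went from 0.899 to 1.10, and the cause was not tested. With one gene identifier per locus, 100% of read positions were taken in place of 9.94%, which follows from joining overlapping models into a locus. Changing read length or overlap rule, one at a time, gave 9.46% to 11.4%. By locus, the strict and nonempty rules moved locus 2 from 0% to 1.37%, locus 3 from 2.10% to 3.52% and locus 4 from 2.81% to 4.61%. Reads of 50 bases gave 0.0549% in locus 2 and reads of 150 bases gave 1.40% in locus 3. One identifier per locus gave 100% in each. Among mouse windows the 2.5 percentile of protein-coding genes was 0, so no low coding count could lie outside. The rank among mouse windows stayed within the 2.5 and 97.5 percentiles, yet it moved from 4.60% with all genes to 33.4% with protein-coding genes only. It was 3.23% on the X chromosome, 3.13% without empty windows and 5.66% for genes wholly inside. The best mouse gene was the same in all 6 alternative chain searches. The planned comparison with Y-linked counterparts gave no value, since the annotation holds none. No paired analysis was possible because the results come from reference files and from no test over samples. Depth of sequencing limits none of these values, and the lack of values per sample limits all comparisons of the design.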

Other observations

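The tests of read assignment and of exon chains were chosen after the files were seen but before their results, and the tests of the overhanging end and of the distance between loci on opposite strands were written after their results.

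Loci 2 and 4 hold long coding exons with close partners in mouse. Exon 34 of locus 2 has 751 bases and its partner in Usp9x has 754. Exon 16 of locus 4 has 773 bases and its partner, exon 17 of Kdm6a, has 779. Locus 2 and Usp9x differ by 3 bases in each of 3 coding exons, and so do locus 3 and Ddx3x in each of 2. The model uc004fsx.1 of locus 4 and the Kdm6a transcript compared differ in 6. Apart from the mouse exon of 135 bases that this model lacks, they differ by up to 15 bases. The second rank of Kdm6b in the search with locus 4 (12 coding exons) exceeds the highest shuffled value of 10. With a tolerance of 3 bases the second gene was Prkdc with 16, so this rank depends on exact equality.

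A hypothesis from these chains is that loci 2, 3 and 4 are the Y-linked relatives of Usp9x, Ddx3x and Kdm6a, which are USP9Y, DDX3Y and UTY. The alternative of a chance match of exon lengths was tested with shuffled chains. For locus 2 the match had 41 coding exons against at most 17 in shuffles, for locus 3 it had 15 against 9, and for locus 4 it had 23 against 10. The number of shuffles that reached the observed match was 0 of 100 for each of the 3 loci, which argues against a chance match of exon lengths. By exon lengths alone, the same chains could also come from another human copy of these genes, such as the X-linked one, whose exons were not analysed here. The location in AZFa, a region of the human Y chromosome, comes from the labels and not from these chains. No sequence was compared.

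A second hypothesis concerns the identifiers. If embryo reads were counted per gene identifier in union mode, overlapping identifiers may leave most reads of the human loci unassigned, and loci 2 to 4 might then look nearly silent beside locus 1. In the annotation, 90.1% of 100-base read positions lay on exons of more than 1 identifier, above the 50% set beforehand. This share follows from the overlap of the annotated models. No embryo read entered it, so it does not test what happened to the reads of the study. With one identifier per locus the ambiguous share was 0%. For loci of one strand that value was fixed by joining overlapping models into a locus, so it does not test whether they overlap. Loci on opposite strands were not joined, and an overlap between them is excluded by the 314070 bp between loci 3 and 4. Whether the study's counts were affected stays open, as the counting settings are not given in the sources used here. No biological explanation was tested.

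The overhang of locus 4 past the indexed sequences, 6221 bp and 6245 bp, has at least 2 candidate explanations. The annotation and the indexed sequences could count from different first bases, or the indexed sequences could lack the end that holds the start codon of 3 models. A shift of the first base has room, since 331485 bp lie before the first model. The explanations cannot be told apart without the sequences. The index also lists 82 bytes per line for SynAZFa and 81 for the other 17 sequences, with 80 bases per line in both.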
